A study of Xenopus tropicalis with 26 samples.

How the data were processed

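Libraries of whole transcriptome target sequencing (WTTS) and RNA-seq libraries of Xenopus tropicalis, the western clawed frog, were compared. Selecting polyadenylated pieces after fragmentation keeps the ends of transcripts, while RNA-seq reads usually come from along the transcript and grow in number with its length. Per the labels' protocols, total RNA was extracted with Trizol, WTTS libraries went through fragmentation, selection of polyadenylated RNA, synthesis of the cDNA strand, sizing and PCR, and libraries were sequenced on Illumina and Ion Torrent instruments. Which library was sequenced on which instrument is not given in the sources used here.

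The deposited table holds raw whole-number counts per feature, not normalized, for 27836 features and 26 libraries. The authors' aligner, counting program, genome build, annotation and use of strand are not given in the sources used here. The features carry XLOC identifiers, a form known from the Cufflinks programs, with a scaffold, start, end and strand, and the files do not pair these identifiers with gene names. None of the identifiers matched the reference gene table at hand, which is on the assembly UCB_Xtro_10.0, so features are named by identifier and position as the table gives them. Whether positions count from 0 or from 1 is not given in the sources used here. Of the 27836 features, 19.1% overlapped a feature on the other strand. For those, reads of both partners cannot be told apart unless strand was used in counting.

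The libraries were grouped from their labels. One pool of RNA from adult frogs of both sexes was used in 7 trials of the WTTS protocol and in 1 RNA-seq library. An adult female gave 2 technical repeats with the final protocol. Embryo pools of 2 families at the 5 stages from 6 to 28 gave 10 WTTS libraries, and the pools of the 3 earliest stages also gave 6 RNA-seq libraries. The families are biological replicates, whereas the trials and the female repeats are technical and their spread says nothing of differences between animals. No pair of replicates was identical or agreed within sampling noise, with chi-square per degree of freedom between 17.9 and 215.

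Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr and the quasi-likelihood F-test, with Benjamini-Hochberg adjusted p below 0.05 as the threshold for a call. All adjusted p-values in the report come from this test. SE values are the absolute log2 change divided by the square root of the F statistic of this test. The 10 embryo WTTS libraries were fitted together with stage as the factor, and the 6 embryo RNA-seq libraries in a separate fit. The family comparison accounted for stage. The comparison of methods used the 12 libraries of the stages with both methods, with the embryo pool as a block, and the method-by-stage tests used the same libraries with an interaction term. The main stage and method-by-stage fits left out the pairing by family or embryo pool, which was an alternative. Normalised CPM values are counts divided by the TMM-scaled library size, on the usual CPM scale. These designs, the list of alternatives and the rule for naming features were written before the data were examined.

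Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), a log2 change of at least 1, family or embryo pool as a replicate block, and leaving out each library, stage or pool. RNA-seq thinned to the depth of the WTTS library of the same pool, and fits without features rich in WTTS reads, were added after seeing the data. Libraries were thinned by 1 random draw of their counts with a fixed seed. Agreement between libraries was measured as the Spearman correlation across features with a summed count of at least 10. Features are not independent replicates, so no p-value is given for it. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

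The families pair the samples, since the labels give the same 2 families at every stage. Deviations from the stage means of 9854 features with a mean of at least 8 CPM correlated between stages of a family in all 10 pairs of WTTS stages, with a mean of 0.284 and a range from 0.114 to 0.415. In RNA-seq the 3 correlations lay between 0.223 and 0.571.

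The naming rule took, per direction, up to 5 features past the threshold with a gene symbol, with group values that did not overlap and a mean log2 CPM of at least 3, in order of the size of change. For the family and method-by-stage tests it took the smallest p, without the condition on overlap. The files do not hold gene symbols, so this condition was dropped and the 2 leading features in each direction were taken by identifier, with a mean log2 CPM of at least 3 in these tests too. Features outside the rule were chosen after their values were seen and are marked as such. Fixed lists of developmental, germ line and tissue genes could not be used without gene names, so the list tests and the comparison of lists between the female and the adult pool were not run. Alternative polyadenylation was not analysed here, since the table holds one value per feature and library.

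A fold against a group with 0 counts is given as a lower bound against 3 counts over the libraries of that group. Shares of single libraries carry exact (Clopper-Pearson) 95% binomial intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. In the embryo WTTS libraries, of 1536128 to 6276132 counts, 3 counts correspond to between 0.478 and 1.95 CPM.

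The tests were checked on simulated counts with the library sizes and dispersion of the real libraries. Each feature had a single mean over all libraries, and known changes were added to a small part of the features. With 14013 features, the WTTS test of stage 11 against 8 recovered 0% of 2-fold, 28.6% of 4-fold and 81.5% of 8-fold changes. With 19413 features, the RNA-seq test recovered 13.4%, 55.9% and 62.7%. The family test on 14013 features recovered 50.9%, 97.2% and 98.5%, the method test on 17498 features 38.5%, 72.9% and 90.2%, and the method-by-stage test on 20485 features 0%, 10.8% and 41.4%. Between 3.13% and 7.69% of simulated calls were false. In the simulated WTTS test of stage 11 against 8, only 78, 63 and 54 features were changed 2-fold, 4-fold and 8-fold. The real tests of these stages called 21.4% of features in WTTS and 58.5% in RNA-seq. These recoveries therefore do not give the power of the real tests.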

Results

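Gene expression was measured as read counts over 27836 features in 26 libraries. The adult pool gave 7 libraries of trials of whole transcriptome target sequencing (WTTS), of 8364595 to 42424000 counts, and 1 RNA-seq library of 73522777 counts. The 2 repeats of the adult female held 11403853 and 22287985 counts. The 10 embryo WTTS libraries held 1536128 to 6276132 counts and the 6 embryo RNA-seq libraries 110710673 to 131001449. In the usual staging of Xenopus, stages 6 and 8 are cleavage and blastula embryos, stage 11 is a gastrula, stage 15 a neurula and stage 28 a tailbud embryo. No read fell on 1630 features in any library.

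More features were detected in embryo RNA-seq libraries than in the shallower embryo WTTS libraries, and the order turned at an equal total count, mainly at stages 6 and 8. Embryo WTTS libraries held at least 1 count for 18308 ± 911 features (SD, n = 10, stages 6 to 28), and embryo RNA-seq libraries for 21667 ± 1206 (SD, n = 6, stages 6 to 11). Thinned to 1536128 counts each, WTTS libraries held 16714 ± 762 features and RNA-seq libraries 14604 ± 1265. In the pools with both methods, the thinned values were 16058 to 17074 in WTTS and 13648 to 13871 in RNA-seq at stages 6 and 8, and at stage 11 they were 16272 and 17833 in WTTS and 16001 and 16445 in RNA-seq. Only the total count was matched. At that depth the adult RNA-seq library held 18567 features and the 7 trials 13796 ± 2648 (SD, n = 7).

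The trials asked how the WTTS protocol changed the transcripts counted from one RNA pool. In trials 2, 3 and 4 a few features took a large part of all counts. XLOC_013799, on scaffold_4 from 20235635 to 20248437, minus strand, took 39.1% (exact 95% interval 39.11 to 39.14), 33.9% (33.88 to 33.93) and 31.5% (31.43 to 31.49) of counts. It took 0.261% of trial 7 and 0.0468% of the adult RNA-seq library. XLOC_014822, on scaffold_4 from 137366577 to 137374482, minus strand, took 21.7% (21.71 to 21.73) of trial 2, 15.7% (15.64 to 15.67) of trial 3 and 2.71% (2.70 to 2.73) of trial 4, against 0.0475% of trial 7 and 0.0140% of RNA-seq. The 10 largest features together held 13.2% of trial 1, 72.1% of trial 2, 66.3% of trial 3, 47.9% of trial 4, 17.4% of trial 5, 6.72% of trial 6 and 7.66% of trial 7, against 6.48% of RNA-seq. The Spearman correlation across features with the RNA-seq library was 0.690, 0.751, 0.663 and 0.746 in trials 1 to 4 and 0.825, 0.853 and 0.865 in trials 5 to 7. Trials 6 and 7 had a Spearman correlation of 0.966 with each other. Each trial was a single library, so protocol and library differences cannot be separated. XLOC_013799 and XLOC_014822 were chosen after their values were seen.

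**Figure D1:**
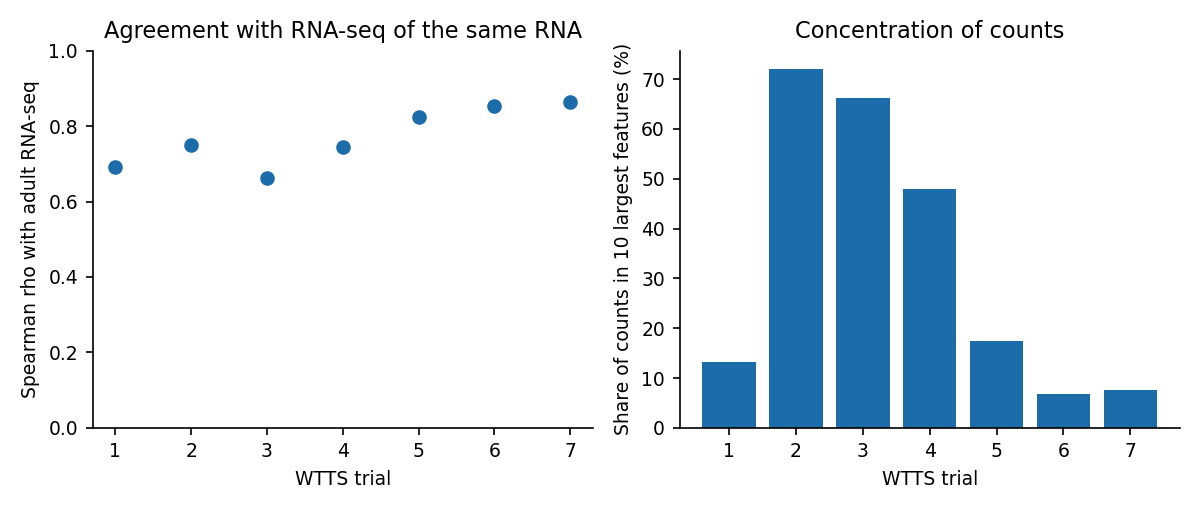
The left panel plots the Spearman correlation across features of each WTTS trial with the RNA-seq library of the same adult RNA, and the right panel the percent of counts held by the 10 largest features of each trial. The Spearman correlation lay between 0.663 and 0.751 in trials 1 to 4 and between 0.825 and 0.865 in trials 5 to 7, and the 10 largest features held 72.1% of trial 2 and 6.72% of trial 6.

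Repeats of the female frog asked how far WTTS repeats itself, and the families how far embryo pools differ. The female libraries had a Spearman correlation of 0.966. WTTS libraries of the 2 families had Spearman correlations of 0.947 at stage 6, 0.937 at stage 8, 0.896 at stage 11, 0.911 at stage 15 and 0.928 at stage 28. RNA-seq libraries of the families reached 0.982, 0.984 and 0.976 at stages 6, 8 and 11. Between methods, the same embryo pool gave values from 0.816 to 0.844. Thinned to 1536128 counts, the female value was 0.927 and the family values of WTTS lay between 0.873 and 0.928.

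Between cleavage and blastula, stages 6 and 8, no feature passed the threshold in either method. In WTTS the edgeR test called 0 of 14013 features, with 338 at an unadjusted p below 0.05, DESeq2 and limma-voom also called 0, and edgeR with no filter on low counts called 20. In RNA-seq it called 0 of 19413 features, with 1307 at an unadjusted p below 0.05, while DESeq2 called 79 and limma-voom 0. The changes of the methods were weakly related, with a Spearman correlation of 0.170 over 13691 features.

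Between blastula and gastrula, stages 8 and 11, 1597 features rose and 1403 fell in WTTS, of 14013 tested. Rising features changed by a median log2 of 2.96, or 2.86 with the 119 features at 0 counts at stage 8 set at their bound. The median of falling features was -1.92. Of the 1597, 141 had at most 3 counts in the 4 libraries of stages 6 and 8 together. XLOC_007837, on scaffold_2 from 92296120 to 92302403, minus strand, had 0 counts at stage 8 and 1108 ± 164 normalised CPM at stage 11 (SD, n = 2). That was at least 2092-fold higher (adjusted p = 3.84e-06), and it reached 5949 ± 1303 CPM at stage 15 and 7378 ± 178 at stage 28. It overlaps a feature on the other strand.

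XLOC_005172, on scaffold_1424 from 8043 to 10383, minus strand, had 0 counts at stages 6 and 8 and 264 ± 207 CPM at stage 11 (SD, n = 2), at least 498-fold higher than at stage 8 (adjusted p = 0.000184). Its mean was 368 ± 140 CPM at stage 15 and 50.4 ± 37.1 at stage 28. XLOC_027235, on scaffold_9 from 63679243 to 63688984, minus strand, fell from 205 ± 35.4 to 4.58 ± 0.703 CPM, with a log2 change of -5.45 (SE 0.38, adjusted p = 5.75e-06). XLOC_010758, on scaffold_3 from 40505066 to 40512069, minus strand, fell from 193 ± 67.2 to 4.54 ± 0.0807 CPM, with a log2 change of -5.40 (SE 0.41, adjusted p = 8.15e-06). Its mean was 24.4 ± 0.147 CPM at stage 28. Without family 1 of stage 8, 1539 features were called, and without family 2 of stage 11, 1940.

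In RNA-seq of the same stages 5880 features rose and 5468 fell, of 19413 tested. The median log2 change was 2.99 for rising features, also with the 245 features at 0 counts at stage 8 at their bound, and -1.51 for falling features. XLOC_000117, on scaffold_1 from 14387997 to 14389577, plus strand, rose from 0.0321 ± 0.0131 to 31.97 ± 2.87 CPM (SD, n = 2), a log2 change of 9.92 (SE 0.43, adjusted p = 2.25e-05). XLOC_011895, on scaffold_375 from 35997 to 41706, minus strand, rose from 0.0308 ± 0.0319 to 31.0 ± 6.50 CPM, with a log2 change of 9.90 (SE 0.73, adjusted p = 0.000115). XLOC_021161, on scaffold_7 from 117307224 to 117313431, plus strand, fell from 769 ± 68.1 to 4.68 ± 0.127 CPM, with a log2 change of -7.36 (SE 0.17, adjusted p = 6.36e-06). Thinned to the depth of WTTS, RNA-seq gave 6620 calls among 12160 features, so part of the larger count came with depth.

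Most features called in WTTS between stages 8 and 11 were also called in RNA-seq, while most called in RNA-seq were not called in WTTS. Of the 1580 features that rose in WTTS and were tested in both, 1347 also rose in RNA-seq, against 407 for independent lists, and 26 fell. Of 1401 that fell in WTTS, 1340 also fell in RNA-seq, against 506, and 4 rose. These 1347 and 1340 features were part of 3527 that rose and 4942 that fell in RNA-seq among the features tested in both. Log2 changes had a Spearman correlation of 0.742 over 13691 features, and 0.820 over the 8392 features with a mean log2 CPM of at least 3 in both. Of the 141 features with at most 3 counts in WTTS before stage 11, 129 also rose in RNA-seq, and 18 had at most 3 counts in the 4 RNA-seq libraries of stages 6 and 8. The limit is far stricter in the deeper RNA-seq. In single libraries of these stages 3 counts are 0.0229 to 0.0271 CPM in RNA-seq and 0.478 to 1.95 CPM in WTTS. The 141 and the 18 are therefore not counts at an equal level. No library was shared between the methods, but the embryo pools were.

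**Figure D2:**
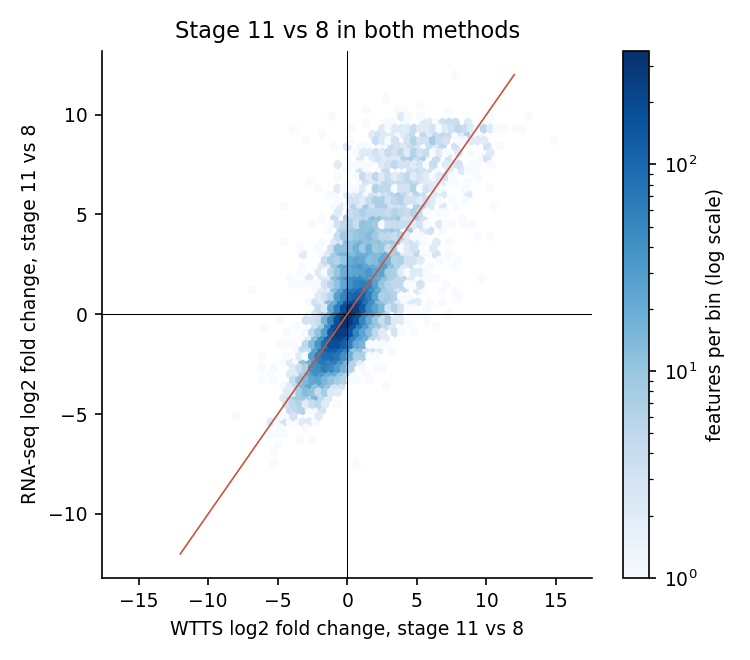
Log2 fold changes of stage 11 against 8 in WTTS (x axis) and RNA-seq (y axis) are shown for the 13691 features tested in both, with darker bins holding more features on a log scale and the red line marking equal change. Points follow the line with a Spearman correlation of 0.742.

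Between gastrula and neurula, stages 11 and 15, 960 features rose and 555 fell in WTTS. The median log2 change was 2.58 for rising features, or 2.55 with the 14 at 0 counts at stage 11 at their bound, and -1.88 for falling features, or -1.86 at the bound. XLOC_005423, on scaffold_1645 from 828 to 10290, plus strand, had 0 counts at stage 11 and 188 ± 19.6 CPM at stage 15 (SD, n = 2), at least 333-fold higher (adjusted p = 6.62e-05). It reached 751 ± 365 CPM at stage 28. XLOC_000499, on scaffold_1 from 62542335 to 62544737, plus strand, had 0 counts at stage 11 and 170 ± 17.8 CPM at stage 15, at least 299.98-fold higher (adjusted p = 6.62e-05). It overlaps a feature on the other strand. XLOC_009914, on scaffold_3 from 52041466 to 52048315, plus strand, went from 8.86 ± 4.08 CPM to 0 counts, at least 11.6-fold lower (adjusted p = 0.00256), and was at 7.24 ± 0.488 CPM at stage 28. XLOC_007792, on scaffold_2 from 87968260 to 87977274, minus strand, went from 2.30 ± 1.81 CPM to 0 counts, at least 3.01-fold lower (adjusted p = 0.0348).

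The call of XLOC_007792 was lost with limma-voom, without family 1 of stage 11 and without either family of stage 15. The number of calls rested on single libraries: 268 features were called without family 1 of stage 11, 585 without family 1 and 548 without family 2 of stage 15. With family as a block, 2600 features were called, 1531 higher and 1069 lower.

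Between neurula and tailbud, stages 15 and 28, 1384 features rose and 1173 fell. The median log2 change was 2.47 for rising features, or 2.45 with the 68 at 0 counts at stage 15 at their bound, and -1.94 for falling features, or -1.93 at the bound. XLOC_027199, on scaffold_9 from 59467542 to 59469301, minus strand, had 0 counts at stage 15 and 358 ± 91.8 CPM at stage 28 (SD, n = 2), at least 468-fold higher (adjusted p = 4.25e-05). XLOC_026402, on scaffold_9 from 86220462 to 86228260, plus strand, had 0 counts at stage 15 and 118 ± 28.5 CPM at stage 28, at least 155-fold higher (adjusted p = 0.000116). XLOC_019325, on scaffold_6 from 105393634 to 105403614, minus strand, went from 15.8 ± 2.24 CPM to 0 counts, at least 42.9-fold lower (adjusted p = 0.000181). XLOC_012434, on scaffold_4 from 9582172 to 9588436, plus strand, had at most 3 counts per library at stages 6 and 8, 227 ± 124 CPM at stage 11 and 797 ± 280 at stage 15. It fell to 2.05 ± 1.93 CPM at stage 28, a log2 change of -8.43 (SE 0.78, adjusted p = 6.58e-05).

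Leaving out 1 library lowered the number of calls between stages 15 and 28 to 813 without family 1 and 1424 without family 2 of stage 15, and to 958 without family 1 and 1419 without family 2 of stage 28. Of the features that rose between stages 8 and 11, 468 fell between stages 15 and 28, against 134 for independent lists, and 53 rose again, against 158. These comparisons share no library, but both come from the same fit and share each feature's estimate of spread. Independent lists are therefore only a rough reference. Of the features that fell between stages 8 and 11, 159 rose between stages 15 and 28, against 139, and 90 fell again, against 117.

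**Figure D3:**
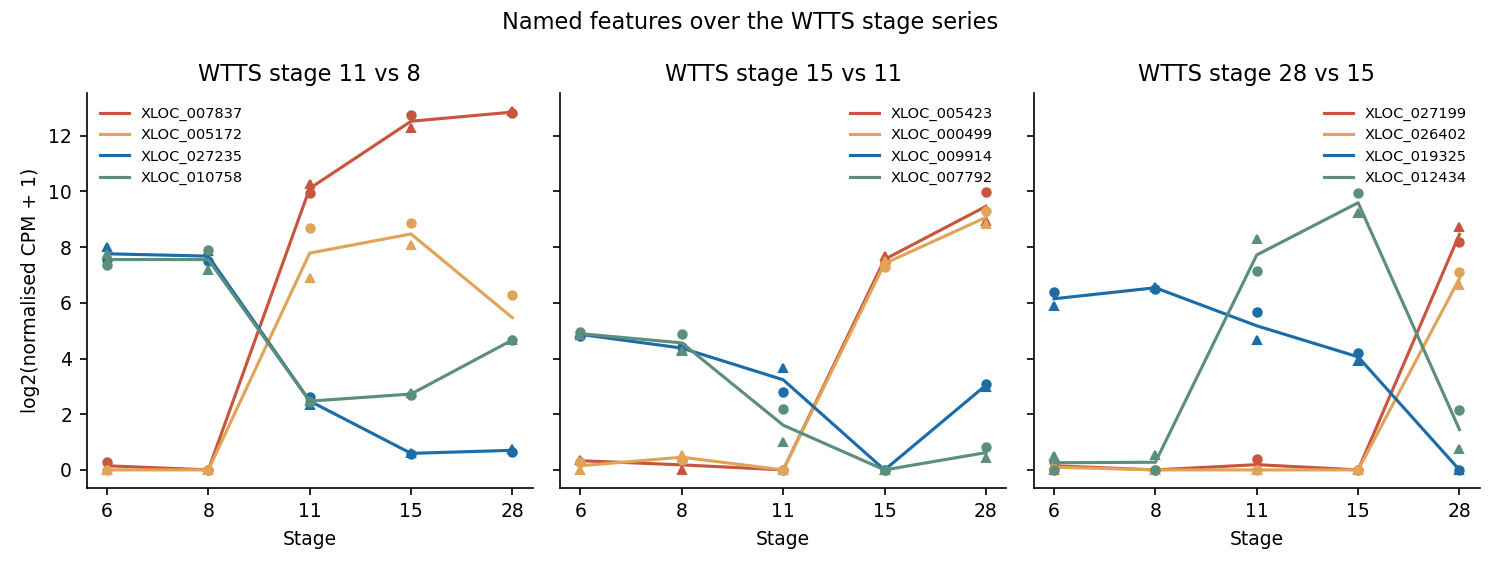
Named features are plotted over the 5 WTTS stages as log2 of normalised CPM plus 1, with circles for family 1, triangles for family 2 and lines joining the means of the log values. XLOC_007837 is at 0 at stage 8 and at 1108 CPM at stage 11, and XLOC_012434 falls from 797 CPM at stage 15 to 2.05 at stage 28.

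Over the whole WTTS series 8694 of 14013 features changed with stage. The stage of the highest mean was 6 for 2444 of them, 8 for 1027, 11 for 972, 15 for 1596 and 28 for 2655. The highest mean was not tested against the next. No feature was called between stages 6 and 8, so the split between these stages rests on untested differences. It also depends on scaling, as the median log2 of stage 8 against 6 was -0.095, and -0.035 with DESeq2 size factors.

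**Figure D4:**
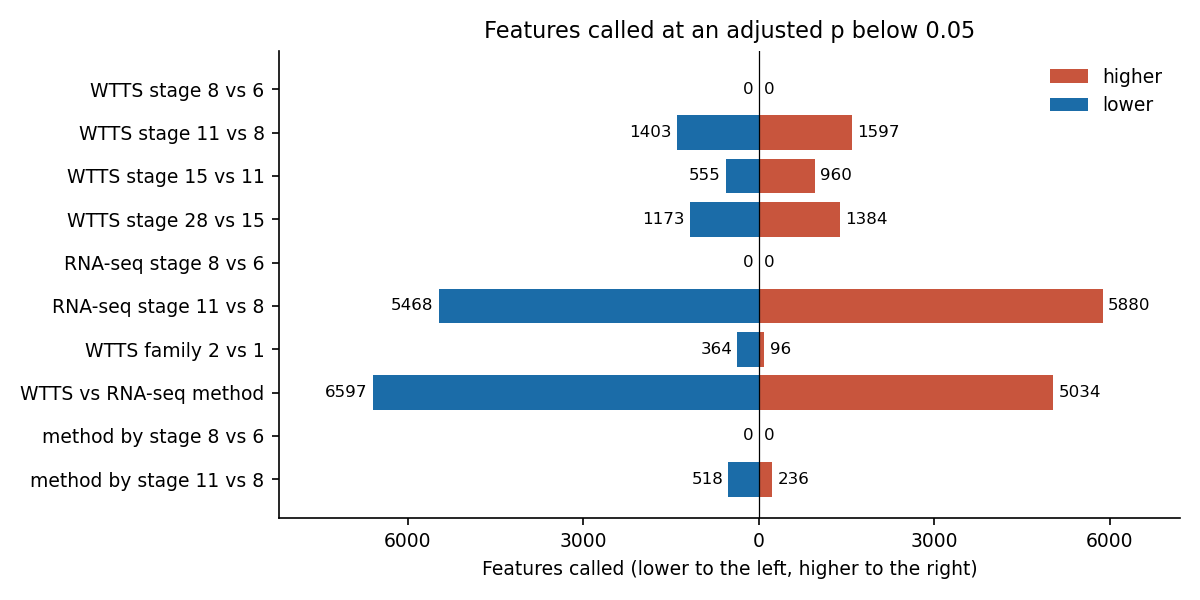
Bars give the number of features called higher (right) or lower (left) at an adjusted p below 0.05 in each comparison, the earlier stage, family 1 or RNA-seq being the reference. Stage 8 against 6 has 0 calls in both methods, and stage 11 against 8 has 3000 in WTTS and 11348 in RNA-seq.

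The families differed at 460 features in WTTS with stage accounted for, 96 higher and 364 lower in family 2. The 5 stages of a family served as its replicates, so the calls concern these 2 families only. Handling shared by the pools of a family cannot be told apart from the family itself. XLOC_013487, on scaffold_4 from 125036072 to 125041414, plus strand, was higher in family 2 by a log2 of 2.55 (SE 0.23, adjusted p = 0.000236), and it overlaps a feature on the other strand. XLOC_008671, on scaffold_225 from 151144 to 158169, minus strand, was higher by 4.16 (SE 0.39, adjusted p = 0.000346), at 71.1 against 6.17 CPM at stage 6 and 0.690 against 0.190 at stage 28. XLOC_027798, on scaffold_97 from 145490 to 147203, plus strand, was lower in family 2, with a log2 of -4.75 (SE 0.28, adjusted p = 5.88e-06). Its values lay between 19.9 and 98.0 CPM in family 1 and between 1.38 and 4.18 CPM in family 2. XLOC_015267, on scaffold_468 from 85465 to 91922, minus strand, was lower with a log2 of -5.31 (SE 0.35, adjusted p = 1.15e-05). All 4 features, chosen by their p in these same libraries, kept their direction in each of the 5 stages by normalised CPM. For XLOC_008671 this rests at stage 28 on 1 count in family 1 and 2 in family 2, too few to tell a direction. At stage 15 it had 1 and 6 counts. The number of calls was 563 without stage 6, 121 without stage 8, 172 without stage 11, 76 without stage 15 and 164 without stage 28. It was 1323 with no filter on low counts, 750 with DESeq2 and 748 with limma-voom.

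The same 6 embryo pools, sequenced with both methods, asked which features the methods count differently. Which library was sequenced on which instrument is not given in the sources used here, so differences between methods include any difference between instruments. Of 17498 features, 5034 were higher and 6597 lower in WTTS, as shares of the library. The median log2 of all features was -0.19, and -0.08 with DESeq2 size factors, so a small shift of all features depends on the scaling. Short features took fewer WTTS reads: the median log2 was -0.99 over 1041 features spanning under 3 kb, -0.31 at 3 to 10 kb, -0.34 at 10 to 30 kb and 0.12 over 6384 features spanning over 30 kb. The span includes introns. The Spearman correlation of the log2 ratio with span was 0.178 across features.

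At the extremes, 298 of 10554 features with at least 5 CPM in WTTS had a WTTS CPM at least 20 times that of RNA-seq, and 277 of 10632 with at least 5 CPM in RNA-seq had the opposite. Of the latter, 22 had 0 counts in WTTS, where 5 CPM would give 103.7 counts. XLOC_022086, on scaffold_7 from 98973032 to 98973681, minus strand, had 345 CPM in WTTS and 0.0212 in RNA-seq (log2 13.78, SE 0.38, adjusted p = 2.44e-08). XLOC_010156, on scaffold_3 from 85284551 to 85288549, plus strand, had 58.3 CPM in WTTS and 1 count in all RNA-seq libraries, a ratio of 37286 with a counting interval from 6692 to 1472700 (adjusted p = 2.65e-08). Both overlap a feature on the other strand. XLOC_015151, on scaffold_4428 from 1858 to 2781, minus strand, had 116 CPM in RNA-seq and 0 counts in WTTS, at least 850.3-fold lower (adjusted p = 7.39e-06). XLOC_017340, on scaffold_5515 from 8 to 4159, minus strand, had 41.9 CPM in RNA-seq and 0 counts in WTTS, at least 306-fold lower (adjusted p = 2.40e-05).

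Without embryo pool as a block, the change between stages 8 and 11 itself differed between methods at 754 of 20485 features. Of these, 236 had a more positive and 518 a more negative change in WTTS. XLOC_010124, a feature of 553143 bp on scaffold_3 from 79671887 to 80225029, plus strand, went from 2.82 ± 0.0316 to 1065 ± 86.3 CPM in RNA-seq (SD, n = 2) and from 20.4 ± 3.49 to 35.2 ± 7.40 in WTTS. The difference of the log2 changes was -7.77 (SE 0.39, adjusted p = 2.39e-06), and the feature overlaps another on its strand. XLOC_011130, on scaffold_3 from 85748251 to 85764518, minus strand, went from 0.960 ± 0.144 to 305 ± 40.0 CPM in RNA-seq and from 17.4 ± 4.58 to 68.0 ± 2.85 in WTTS, a difference of -6.36 (SE 0.38, adjusted p = 8.67e-06). It overlaps a feature on the other strand.

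XLOC_006007, also among the leading falling features of RNA-seq, on scaffold_2 from 18258505 to 18269031, plus strand, fell from 21.8 ± 6.95 to 0.169 ± 0.0139 CPM in RNA-seq and had 1.56 ± 0.545 and 2.61 ± 1.45 CPM in WTTS, a difference of 7.71 (SE 0.77, adjusted p = 0.000526). XLOC_018427, on scaffold_6 from 105538151 to 105591484, plus strand, fell from 127 ± 28.3 to 7.76 ± 1.16 CPM in RNA-seq and had 54.2 ± 8.79 and 37.4 ± 15.4 in WTTS, a difference of 3.49 (SE 0.44, adjusted p = 0.00241). With embryo pool as a block 1422 features differed, 544 with a more positive change in WTTS. DESeq2 gave 1800, 667 more positive and 1133 more negative, and limma-voom 1539, 211 and 1328. Thinned RNA-seq gave 198, and there the larger direction turned, with 134 more positive and 64 more negative. For stage 8 against 6 edgeR called 0 of 20485 features, with 535 at an unadjusted p below 0.05, DESeq2 called 1 and limma-voom 0.

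A pair of features held large parts of single embryo WTTS libraries. XLOC_016359, on scaffold_5 from 8636690 to 8661332, minus strand, took 17.6% of counts (exact 95% interval 17.61 to 17.68) at stage 11 in family 1 and 2.91% (2.88 to 2.93) in family 2. The families were close at stage 15, with 17.5% (17.45 to 17.54) and 16.98% (16.93 to 17.03), and at stage 6 family 1 was the lower, with 0.357% (0.351 to 0.363) against 1.56% (1.55 to 1.57). At stage 8 it took 2.07% and 0.845%, and at stage 28 9.18% and 2.97%. In RNA-seq it took 0.343% and 0.336% of the stage 11 pools. It rose between stages 8 and 11 in both methods, by a log2 of 3.44 in WTTS (SE 1.07, adjusted p = 0.0389) and 1.78 in RNA-seq (SE 0.13, adjusted p = 0.000105), and the difference between the methods was 1.33 (SE 1.13, adjusted p = 0.592). The call in WTTS was lost with limma-voom, without either family of stage 8 and without family 1 of stage 11, where the log2 was 1.25 (adjusted p = 0.404), while the call in RNA-seq was kept in every alternative.

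XLOC_005482, on scaffold_169 from 134765 to 256436, minus strand, was uneven the other way at stage 11, with 0.661% (exact 95% interval 0.654 to 0.669) of WTTS counts in family 1 and 13.6% (13.53 to 13.62) in family 2. In RNA-seq of the same pools it took 0.770% in family 1 and 0.210% in family 2. It rose between stages 8 and 11 in WTTS by a log2 of 3.93 (SE 1.12, adjusted p = 0.0254), while the RNA-seq change of 1.39 did not pass (SE 0.63, adjusted p = 0.0996). The difference between the methods was 2.15 (SE 1.46, adjusted p = 0.480). The call in WTTS was lost with limma-voom, without family 1 of stage 8 and without family 2 of stage 11, where the log2 was 0.871 (adjusted p = 0.566). The RNA-seq change passed with DESeq2, after thinning and without family 2 of stage 11. XLOC_016359 and XLOC_005482 were chosen after their values were seen.

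**Figure D5:**
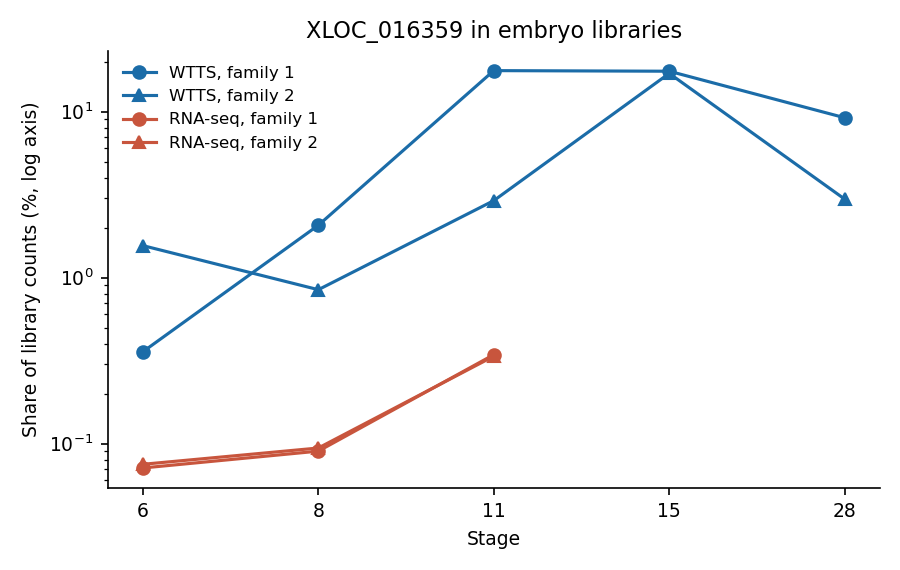
The share of library counts held by XLOC_016359 is plotted on a log axis against stage, in blue for WTTS and red for RNA-seq, with circles for family 1 and triangles for family 2. At stage 11 the WTTS libraries are at 17.6% and 2.91%, and the RNA-seq libraries at 0.343% and 0.336%.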

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

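The tests that thinned RNA-seq, and the test of the spread of WTTS-rich features between families in WTTS, with its repeat at stages 15 and 28, were chosen only after the results they bear on had been seen.

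Between stages 8 and 11 the change differed between methods at 754 features by a test of the difference itself. Overlap with a feature on the other strand argued against counting of the partner's reads as a general cause: the share of overlapping features was 0.743 percentage points lower than in features of matched RNA-seq CPM that were not called, a difference of -0.743 (95% interval -3.74 to 2.41). Thinning RNA-seq to the depth of WTTS could not decide on lower depth as a cause, since thinning leaves the expected log2 difference unchanged. The median share of it left was 0.951 (95% bootstrap interval 0.921 to 0.9753) in 421 of the 518 with a more negative change in WTTS. In 233 of the 236 with a more positive change it was 1.04 (1.02 to 1.06). Of the 518 only 64 were still called, and 97 were not tested. In the 357 tested that lost their call, the median difference went from -4.11 to -3.82 and the median SE from 0.83 to 1.48. This SE follows from the F statistic that decides the call, so its rise is no separate evidence of a larger error. Lower depth of WTTS stays open, also for the 97 features of the 518 that were too low to test after thinning. So does differing use of 3′ ends between stages, which was not tested.

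Among the 11 features taken by the naming rule between stages 8 and 11, the difference of the log2 changes, WTTS minus RNA-seq, was -7.77 for XLOC_010124, -6.36 for XLOC_011130, 7.71 for XLOC_006007 and 3.49 for XLOC_018427. It was -6.11 for XLOC_011895, with an adjusted p of 0.0111 by the edgeR test, and 1.84 for XLOC_021161, with an adjusted p of 0.0467. For XLOC_007837 the fitted difference was 10.04 (adjusted p = 0.0325), a value that depends on the prior count because the feature had 0 WTTS counts at stage 8. For the other 4, XLOC_005172, XLOC_000117, XLOC_027235 and XLOC_010758, the difference did not pass the threshold (adjusted p = 0.707, 0.832, 0.91 and 0.719).

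The 298 features with many WTTS reads for their RNA-seq reads held 24.9% of the WTTS counts at stage 11 in family 1 and 6.32% in family 2, against 0.473% and 0.445% in RNA-seq; without XLOC_016359, the other 297 held 7.21% and 3.41%. Their median absolute log2 ratio between families, taken after adding 1 CPM, was 0.07 (0.0698) in RNA-seq, at percentile 61.8 of matched lists. Adding 1 CPM shrinks this ratio in features with few RNA-seq reads, so it cannot decide on a difference of RNA abundance between families. In WTTS the ratio was 0.68 (0.679), above the 95th percentile of matched lists, 0.487. In the WTTS libraries of stages 15 and 28, which were not used to choose the features, it was 0.886 against a 95th percentile of 0.581. Uneven capture between WTTS libraries is a candidate explanation, and its origin, in priming or in PCR, was not tested. A difference of RNA abundance between families stays open.

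The 277 features with RNA-seq reads and few WTTS reads were compared with features of matched RNA-seq CPM and a similar CPM in both methods. A 3′ end assigned to a feature within 10 kb downstream was argued against as the general cause, since only 20.2% had such a same-strand feature. Of matched features 24.1% had one, a difference of -3.90 percentage points (95% interval -9.03 to 1.52). For those with such a neighbour this cause stays open: the median log2 ratio of WTTS over RNA-seq of the neighbours was 0.10 against -0.17, a difference of 0.27 (-0.77 to 0.83). Reads from a partner on the other strand were also argued against as the general cause, since only 13.7% overlapped such a feature. The difference in this share from matched features was -9.68 points (-14.2 to -4.91). Matching did not include the scaffold, and near a scaffold's end there is no room for a neighbour. XLOC_017340, for instance, lies on the minus strand from position 8. Both differences in share therefore decide nothing. RNA without a poly(A) tail and gaps in the features at 3′ ends stay open and were not tested.

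Other splits of the samples bear on whether calls arise by chance. Of the 16 flips of the family label within stages, 1, the real labels, gave 460 calls and the highest of the others 1, but 16 flips are too few for a share below 0.05. Of the 32 flips of the method label within embryo pools, 1, the real labels, gave 11631 calls and the highest of the others 0. That share of 0.03125 is the lowest that 32 flips can give. The other flips put the difference between methods into the spread, so their lack of calls says little about chance. The difference between methods includes any difference between instruments.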

How the results depend on the processing

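RNA-seq thinned to the depth of WTTS and fits without WTTS-rich features were chosen after seeing the data. No feature taken by the naming rule changed its direction in the tests it was taken from, and neither did XLOC_016359 and XLOC_005482 between stages 8 and 11, but their calls in WTTS were lost in 4 and 3 alternatives. The larger direction of the calls was not stable. It turned in the method-by-stage test of stages 8 to 11 with thinned RNA-seq, with 134 more positive and 64 more negative in WTTS. In RNA-seq between stages 8 and 11 it turned with DESeq2 (5319 higher, 5621 lower), thinned (3269 and 3351), without family 1 (3925 and 4367) or family 2 (4027 and 4297) of stage 8 and without family 2 of stage 11 (4607 and 4857). In WTTS it turned between stages 8 and 11 without family 2 of stage 8 (1007 and 1042), and between stages 15 and 28 with DESeq2 (1234 and 1321) and without family 1 (402 and 411) or family 2 (641 and 783) of stage 15. With thinned RNA-seq, 74 of 7683 features called in RNA-seq between stages 8 and 11 had the other sign, none of them past the threshold. Of 123 recomputed values of the main results 81 stayed within 1.5 times or within 1 SD. Part of these 81 are 0 calls that stayed at 0 in the tests of stages 6 to 8. There the alternative of a log2 change of at least 1 reuses the main fit and could give nothing else. Of 291 for features taken by the naming rule 287 kept their call, the exceptions being 4 for XLOC_007792, named in the report. This high share is partly built in, since the features were chosen for their changes in the same data. For them the alternative of a log2 change of at least 1 also repeats the main fit. Without a filter on low counts 20 features were called in WTTS between stages 6 and 8, 2281 between stages 11 and 15 and 1323 between families. DESeq2 called 79 features in RNA-seq between stages 6 and 8, 750 between families, and 1 and 1800 in the method-by-stage tests of stages 6 to 8 and 8 to 11. Limma-voom called 748 between families and 1539 in the latter test, 13.7% of them with a more positive change in WTTS against 31.3% by edgeR. A log2 change of at least 1 left 273 calls between families. Thinned RNA-seq gave 6620 calls between stages 8 and 11 and 198 in the method-by-stage test, 67.7% of them more positive, and had fewer features to test.

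With the family as a replicate block, or the embryo pool for the method-by-stage test, calls rose to 2600 between stages 11 and 15 and to 1422 in the method-by-stage test of stages 8 to 11. Counts other than the 2600 and the 1422 moved by no more than 1.5 times. In WTTS they rose from 3000 to 4001 between stages 8 and 11 and from 2557 to 3723 between stages 15 and 28. In RNA-seq between stages 8 and 11 they rose from 11348 to 12282. Leaving out 1 library, stage or pool gave 1539 to 2371 calls in WTTS between stages 8 and 11, 268 to 1455 between 11 and 15, and 813 to 1424 between 15 and 28. It gave 8292 to 10891 in RNA-seq between 8 and 11, 76 to 563 between families and 10538 to 11645 between methods. The lone library left in a stage is assumed to vary like the other stages. The cause was not tested for any of these values.

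The Spearman correlation between the changes of the methods from stage 6 to 8 was 0.257 for features with a mean log2 CPM of at least 3, 0.138 in family 1, 0.154 in family 2, and 0.0900 and 0.0610 across families. From stage 8 to 11 it was 0.820 for those features, 0.781 with means of log2 CPM, 0.720 in family 1, and 0.686 and 0.703 across families. The median Spearman correlation of the trials with RNA-seq was 0.751, and 0.642 after thinning and 0.552 with RNA-seq counts divided by span. That of the female repeats was 0.927 after thinning. The median number of features in embryo WTTS libraries was 18207, 13028 at a count of at least 5 and 16578 after thinning. The tests of the fixed gene lists and the comparison of these fixed lists between female and pool were not run, since the files do not pair identifiers with gene names.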

Other observations

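The tests of neighbouring features, spans and adult levels were set before their results were seen, while the repeat without any pair under 10 kb apart, the spans of falling features and of later stages, the adult level of rising features and the account of DESeq2 calls were added to them afterwards.

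Features that rose between blastula and gastrula in WTTS lay next to each other more often than random placement would give. Of 13337 neighbouring pairs of tested features, 251 held 2 rising features, against a median of 173 and a central 95% of 150 to 196 over 10000 shuffles. Without same-strand pairs under 10 kb apart, 213 remained against 126 to 169. Transcripts split over 2 features closer than 10 kb thus do not explain all of the excess, and wider splits were not tested. Without any pair under 10 kb apart, 171 remained against 85 to 122. Falling features showed no such excess, with 143 pairs against 113 to 154. Clusters of co-regulated genes are a hypothesis that may account for this, and gene names would be needed to follow it.

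There were 12 runs of at least 4 neighbouring rising features, holding 50 features. Neighbours here are consecutive tested features at any distance, with untested ones skipped. The runs spanned from 34.8 kb to 3261 kb, the longest being 5 features on scaffold_1. The number of runs to be had from random placement was not computed. On scaffold_7 a run of 5 features within 53.6 kb, from 94439056 to 94492671, lay on both strands, and all 5 also rose in RNA-seq. Its median log2 change in WTTS was 4.54. On scaffold_9 a run of 4 minus-strand features from 21826721 to 22047082 rose by a median of 5.19, and all 4 rose in RNA-seq. On scaffold_8 a run of 4 plus-strand features within 34.8 kb, from 70643176 to 70677968, rose by a median of 7.00, and 2 of them rose in RNA-seq.

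Between stages 8 and 11, rising features had shorter spans than features of matched CPM, though not shorter than the median of 10820 bp over all 27836 features of the table. In WTTS the 1597 features that rose between stages 8 and 11 spanned a median of 18951 bp, below the central 95% of matched lists, 20662 to 23539. The 5880 that rose in RNA-seq spanned 15499 bp, against 16297 to 17388. Falling features spanned 16627 bp in WTTS, below their matched lists at 21159 to 24436, but 21208 bp in RNA-seq, above theirs at 19660 to 20652. Features rising between stages 11 and 15 spanned 18588.5 bp, below 20742 to 24692, and those rising between stages 15 and 28 spanned 24934.5 bp, above 20934.5 to 24136. Shorter genes than others of the same level in early zygotic transcription are a hypothesis in line with the rising features of both methods at 18951 and 15499 bp, while the falling features of WTTS show that a short span is not particular to rising ones there.

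Features that fell in both methods between stages 8 and 11 had a higher ratio of the adult female over the adult pool than matched features. The log2 ratio of the female over the pool trials, for 1340 such features, exceeded that of lists matched on adult CPM by a median of 0.37 (0.368) over the 7 trials, and lay above the central 95% of the lists in each. The excess lay between 0.17, against trial 6, and 0.66, against trial 1. The 1347 features that rose in both methods lay below their matched lists, by differences from -0.48, against trial 2, to -0.16, against trial 7. The tissue behind this difference was not tested. It rests on 1 female frog, and the protocol of the trials differed from that of the female libraries.

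Of the 79 features that DESeq2 called in RNA-seq between stages 6 and 8, 52 were higher at stage 8 with a median log2 change of 0.75, and 27 were lower with a median of -0.80. In WTTS of the same pools 33 of the 51 higher features tested and 22 of the 27 lower ones had the same sign. None of them was called by edgeR in either method.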
